A study of Pseudomonas aeruginosa PAO1 with 9 samples.

How the data were processed

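RNA was sequenced from 9 cultures of *Pseudomonas aeruginosa* PAO1, with 3 cultures each in the control, DAS and DAE groups. Groups were taken from the sample labels. The titles of the DAE samples abbreviate the compound as DAO, while their other labels name DAE. The series text also mentions farnesol groups, which no sample label carries, and these played no part here. Per the labels' protocols, RNA was extracted with Trizol and made into strand-specific Illumina libraries, and the labels call the growth phase exponential. The labels state triplicates without saying whether the cultures came from separate starter cultures or days, so p-values measure only the spread between these cultures.

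Per the submitters' processing notes, Bowtie2 2.0.6 and TopHat2 2.0.9 were used. The counting tool, its strand setting and the handling of reads that map to several genes are not given in the sources used here. For each sample the authors deposited a table with an expected count and an FPKM value per gene. Expected counts are estimates that need not be whole, and 4.77% to 10.7% of them per library were fractional. They were rounded to whole numbers. FPKM values deposited by the authors are scaled to coding length and to library depth, as their name states. The tables list 5572 coding genes with positions on the PAO1 chromosome, and 5571 of the start positions equal those of the RefSeq annotation of assembly ASM676v1, from which symbols were taken. All 5572 lengths are multiples of 3, so they are coding lengths. PA4823 had no value in DAE replicate 1 and was left out. Genes that overlap or lie antisense to each other, and near-identical copies such as the phz operons, share reads in a way that these tables do not resolve.

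Total counts were 13.6 M to 17.4 M per library, and 0.036% to 0.395% of genes had fewer than 10 counts. No pair of libraries agreed within sampling noise, since chi-square per degree of freedom was at least 12.6 within groups, and each library correlated best with a library of its own group.

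The main test was edgeR 4.0.16 in R 4.3.3 with TMM factors, filterByExpr (minimum count 10, minimum total 15), and the quasi-likelihood F test. All 9 libraries entered 1 fit with a coefficient per group. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The test plan had named limma on FPKM for the case that the files held no counts. As the files held expected counts, the count test was used and limma 3.58.1 on log2(FPKM + 1) became an alternative. The standard error of a log2 fold change was its size divided by the square root of F. That of a list median was taken over list members as if independent, and so does not measure the spread between cultures. On simulated counts with 200 changed genes among 5567, the test recovered 56.7% of 1.5-fold, 98.5% of 2-fold and 100% of 4-fold changes for DAS versus control. It recovered 62.7%, 97% and 100% for DAE versus control, and 44.8%, 98.5% and 100% for DAS versus DAE. False calls made up 6.59%, 5.98% and 1.82% of the simulated calls, in the same order of comparisons. The count of genes in opposite directions used the larger of a gene's p-values against the control, adjusted over all genes. It returned 200 genes when 200 of 5567 were simulated so. Their simulated changes were far larger than the noise, so this says little about small changes.

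Before the data were examined, 27 gene lists with 685 entries were fixed from general knowledge of the species, and 621 entries matched a gene by symbol or locus tag. The efflux and sulfur lists lost the most entries. No gene is in more than 1 list. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. A further list of 9 stationary-phase markers, for the weighing of growth phase alone, was chosen later, once the tables were at hand. No cell type markers were used, the samples being pure cultures.

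Genes named in the text follow a rule fixed in advance. For each comparison it takes the 10 largest rises and 10 largest falls among called genes whose libraries did not overlap between groups and that reached 10 CPM in the higher group. It adds up to 4 called genes with the smallest adjusted p of each called list, and 21 genes named in every case (*lasI*, *lasR*, *rhlI*, *rhlR*, *pqsA*, *mvfR*, *lasB*, *rhlA*, *lecA*, *hcnA*, *phzM*, *phzS*, *pvdS*, *pchR*, *thiC*, *ribD*, *bioB*, *folE2*, *mexE*, *mexG*, *katB*). Genes outside the rule are named where they are the exceptions of a list. The closing observations also name terminal oxidase, oxidative stress and stationary-phase genes outside it.

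The alternatives fixed in advance were DESeq2 1.42.0 with its size factors, no filter on low counts, a mean FPKM of at least 10, limma on FPKM with pseudocounts of 1, 0.1 and 5, with no filter, with median centring and with quantile normalization, the replicate number as a block, robust=TRUE in the quasi-likelihood fit, only the 6 libraries compared, and each library left out in turn. Thresholds of adjusted p under 0.01 and of an absolute log2 fold change of at least 1 were also tried. The pseudocount, centring and quantile alternatives were run on the limma fit and so change the tool as well. A fit with library totals and no TMM factors was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.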

Results

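Transcriptomes were measured by RNA sequencing in 9 cultures of *Pseudomonas aeruginosa* PAO1, a laboratory reference strain of this opportunistic pathogen. Of these, 3 cultures were untreated controls, 3 received diallyl sulfide (DAS) and 3 received diallyl ether (DAE). Both compounds carry a pair of allyl groups, joined through a sulfur atom in DAS and through an oxygen atom in DAE. Each was added at 0.625 µl/mL to 50 mL of LB medium, and all cultures were shaken at 180 rpm and 37 °C for 5 h. The deposited tables gave an expected read count and an FPKM value for up to 5572 protein-coding genes. Total counts lay between 13.6 M and 17.4 M per library, and 5567 genes entered the tests. Across genes, log2 CPM values of libraries of the same group correlated at 0.9887 or above. The correlation was 0.9364 to 0.9554 between control and DAE libraries, 0.8273 to 0.8578 between DAE and DAS libraries, and 0.7208 to 0.7704 between control and DAS libraries. The 10 most abundant genes held 14.97% to 15.65% of the counts in control libraries, 10.9% to 13.5% with DAE and 7.84% to 9.07% with DAS. Levels below are CPM values, the standard depth-scaled counts, with TMM factors applied, as mean ± SD with n = 3, and changes are log2 fold changes with their standard error (SE).

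The first comparison asked how exposure to DAS altered the transcriptome. Genes of quorum sensing, of the secreted products it controls and of a type VI secretion locus were far lower in DAS cultures, while a multidrug efflux operon, ribosomal protein genes and most chaperone genes were higher. The ribosomal and chaperone lists were called by camera with its preset correlation, and both calls were lost at adjusted p = 0.425 and 0.563 with an estimated correlation. The largest fall was that of *lecA* (PA2570, position 2905182 to 2905550 on the PAO1 chromosome), which encodes a galactose-binding lectin. It fell from 1090 ± 145 CPM in controls to 2.79 ± 0.677 CPM with DAS (log2 fold change -8.61, SE 0.32, adjusted p = 1.75e-10). The alkaline protease gene *aprA* (PA1249, 1355631 to 1357070), at 31100 ± 1140 CPM in controls, was at 144 ± 30.5 CPM with DAS (log2 fold change -7.75, SE 0.23). The largest rise was that of *mexC* (PA4599, 5154237 to 5155400), from 4.26 ± 0.41 to 1050 ± 193 CPM (log2 fold change 7.94, SE 0.19, adjusted p = 1.58e-11). It was followed by *fhp* (PA2664, 3012592 to 3013773), the gene of a flavohemoprotein that detoxifies nitric oxide, which went from 18.3 ± 1.61 to 1730 ± 469 CPM (log2 fold change 6.56, SE 0.22). The neighbours of *mexC*, *mexD* and *oprJ*, rose by 6.23 and 5.23 on the log2 scale. Other genes among the 10 largest falls were *lecB*, of a fucose-binding lectin (-6.58), the pilin gene *flp* (-6.60) and the aerotaxis transducer gene *aer2* (-6.56). In all, 4413 of 5567 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2287 of them higher and 2126 lower with DAS. Of these, 2402 changed at least 2-fold, with 1113 higher and 1289 lower. With library totals in place of TMM factors the split was 3090 higher and 1479 lower, because that scaling placed the median gene at 0.525 on the log2 scale, against 0.051 with TMM.

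Quorum sensing, by which this species couples gene expression to cell density, was lower at most of its tested genes. Of 19 genes for its regulators and signal synthesis, 17 were lower with DAS and 1 was higher, with a median log2 fold change of -2.28 (camera adjusted p = 2.34e-12, and adjusted p = 0.0233 with an estimated correlation). The regulator genes *lasR* (-1.49, SE 0.10), *rhlR* (-2.28, SE 0.13) and *mvfR* (-2.12, SE 0.10) fell, as did the signal synthase gene *rhlI* (-1.93, SE 0.14). Of the quinolone signal operon, *pqsD* fell from 776 ± 22.6 to 25.8 ± 0.808 CPM, and *pqsA* fell from 675 ± 80.2 to 64.1 ± 20.5 CPM. The exception was *lasI*, which makes the long-chain homoserine lactone signal and rose from 524 ± 94.5 to 743 ± 20.3 CPM (0.50, SE 0.14, adjusted p = 0.00544). The remaining gene, *vfr*, was at 0.10 (adjusted p = 0.438). Among 25 genes for secreted factors under quorum-sensing control, 24 were lower and none was higher, with a median of -3.44 (camera adjusted p = 3.78e-19, and adjusted p = 0.0233 with an estimated correlation). The elastase gene *lasB* fell from 1380 ± 146 to 21.2 ± 1.32 CPM (-6.03, SE 0.15) and the rhamnolipid gene *rhlA* from 1650 ± 88.9 to 59.7 ± 26.9 CPM (-4.79, SE 0.27). The protease gene *lasA* (-5.45), the chitinase gene *chiC* (-5.78) and the hydrogen cyanide synthase gene *hcnA* (-2.39) were lower as well. The gene outside the call was *plcN*, at 0.04 (adjusted p = 0.771).

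**Figure D1:**
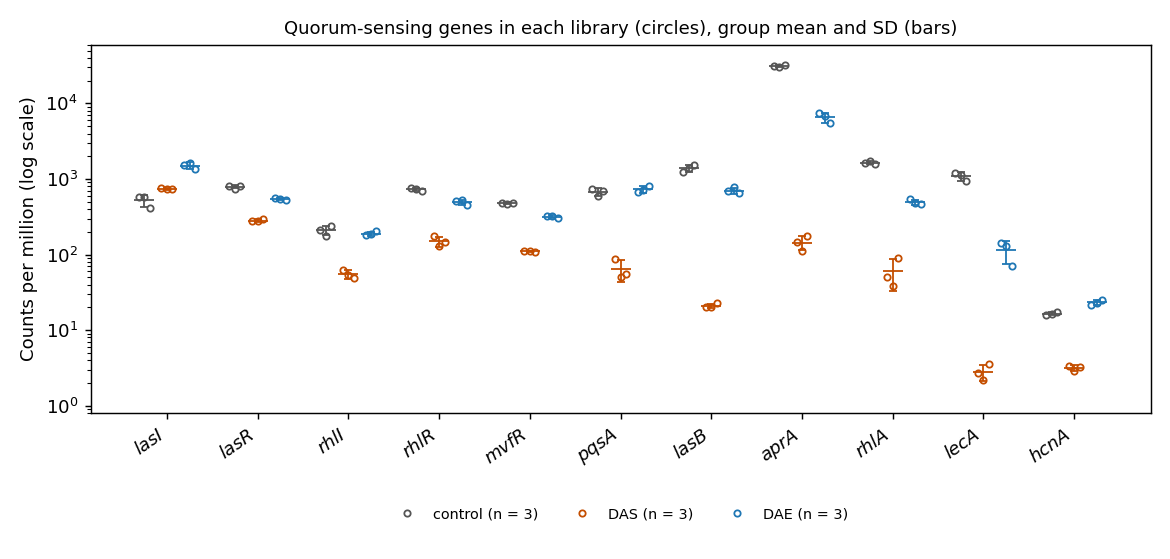
Level of 11 quorum-sensing genes in CPM on a log axis, for the 3 libraries of each group (circles, control grey, DAS orange, DAE blue) with the group mean and SD (bars). With DAS, *lasB* was at 21.2 CPM against 1380 CPM in controls and 704 CPM with DAE, whereas *lasI* was highest with DAE at 1510 CPM.

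The second type VI secretion locus, a contractile apparatus that injects proteins into neighbouring cells, was lower at 15 of 15 tested genes, with a median of -3.83 (camera adjusted p = 2.26e-19, and adjusted p = 0.0306 with an estimated correlation). Its genes PA1662 and PA1665 went from 363 ± 16.7 to 23.3 ± 1.9 CPM and from 110 ± 3.96 to 6.85 ± 0.323 CPM. Of 18 genes of the first locus, 1 was higher and 1 was lower, against 7 and 0 with library totals. Phenazine genes, which make redox-active pigments such as pyocyanin, were lower at 16 of 17 members with a median of -2.89 (camera adjusted p = 6.26e-06, and adjusted p = 0.425 with an estimated correlation). Adjusted over the list alone, 17 of them were lower, the added gene being *phzG1*. *phzM* fell by 2.71 (SE 0.14) and *phzS* by 2.72 (SE 0.19) on the log2 scale. The phz genes exist in near-identical operon copies whose reads cannot be told apart with certainty, so the value of each copy is uncertain. Summed over both copies, each of the 7 gene pairs was at 0.0393 to 0.163 of its control level, below every control library.

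Siderophore genes, for the iron chelators pyoverdine and pyochelin, were lower too. For pyoverdine 16 of 17 genes were lower, with a median of -1.23 (camera adjusted p = 0.00395, and adjusted p = 0.575 with an estimated correlation), and for pyochelin 9 of 9, with a median of -2.26 (camera adjusted p = 0.000108, and adjusted p = 0.426 with an estimated correlation). The biosynthesis genes *pvdH* (-3.34, SE 0.16) and *pchF* (-3.39, SE 0.15) and the pyochelin receptor gene *fptA* (-1.98, SE 0.12) were among them. The regulators changed less, *pvdS* by -0.75 (SE 0.18) and *pchR* by -0.80 (SE 0.18). Both calls were lost with library totals, where *pvdS* was at -0.279 and *pchR* at -0.32, and in the limma fits of FPKM values that were neither centred nor quantile normalized. Over the alternative fits the adjusted p of *pvdS* ranged from 0.000255 to 0.164 and that of *pchR* from 1.86e-05 to 0.156.

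Further lists were lower with DAS by camera, and for each of them the call was lost with an estimated correlation. Flagellar and chemotaxis genes were lower at 36 of 39 members (median -1.15, camera adjusted p = 2.05e-05, and adjusted p = 0.553 with an estimated correlation), and the flagellin gene *fliC* went from 25200 ± 1770 to 4640 ± 625 CPM. Branched-chain amino acid catabolism was lower at 13 of 14 genes (median -1.67, camera adjusted p = 0.0108, and adjusted p = 0.563 with an estimated correlation), with *mmsB* at -5.17 (SE 0.40) and the regulator *mmsR*, named after its values were seen, higher at 0.79. The R- and F-type pyocin region, which encodes phage tail-like bacteriocins, was lower at 29 of 34 genes (median -1.20, camera adjusted p = 0.0101, and adjusted p = 0.704 with an estimated correlation). Exopolysaccharide genes were lower at 20 of 31 members and higher at 6 (median -0.65, camera adjusted p = 0.0303, and adjusted p = 0.425 with an estimated correlation). The lower members included *pslF* (-2.37) and *pslD* (-2.31) of the Psl polysaccharide, while all 6 higher ones with TMM belonged to the Pel polysaccharide, among them *pelD* (1.81), named after its values were seen. With library totals the split was near even, at 11 higher and 13 lower (median -0.18). Denitrification and anaerobic arginine genes were lower at 19 of 31 members and higher at 3 (median -1.08, camera adjusted p = 0.0303, and adjusted p = 0.704 with an estimated correlation). Here the arginine deiminase genes *arcA* (-3.87, SE 0.22), *arcB* (-3.82, SE 0.22) and *arcC* (-4.20, SE 0.21) fell. The nitrate reductase gene *narG* was at 116 to 167 CPM with DAS against 489 to 1030 CPM in controls. *narH* was at 77.2 to 110 CPM against 246 to 486 CPM, and the transporter gene *narK2* at 34 to 36 CPM against 222 to 473 CPM. The 3 higher genes, named after their values were seen, were *norB* of nitric oxide reduction (1.65) and the regulatory genes *nirQ* (2.05) and *dnr* (0.43). Without control replicate 1 or control replicate 2 the call of this list was lost, at adjusted p = 0.064 and 0.0514, within a range of 0.000935 to 0.064 over the alternative fits. With library totals 6 of its genes were higher and 17 lower.

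Ribosomal protein genes were higher with DAS at 53 of 53 members, with a median of 1.68 (camera adjusted p = 1.83e-12, and adjusted p = 0.425 with an estimated correlation). *rplM* went from 129 ± 9.69 to 741 ± 103 CPM. B vitamin and cofactor genes were higher at 31 of 38 members and lower at 2, *panE* and *pdxH* (median 1.02, camera adjusted p = 5.89e-05, and adjusted p = 0.39 with an estimated correlation). The biotin synthase gene *bioB* rose from 180 ± 17.7 to 910 ± 131 CPM (2.34, SE 0.15), the thiamine gene *thiC* rose by 1.16 (SE 0.10) and the riboflavin gene *ribD* by 0.47 (SE 0.15). The folate gene *folE2* was at 0.08 (SE 0.10, adjusted p = 0.473), but it was called higher with library totals (0.556) and in most limma fits, with adjusted p from 0.000512 to 0.881 over the alternative fits. Sulfur assimilation and cysteine or methionine synthesis was higher at 18 of 25 genes and lower at 4 (median 1.06, camera adjusted p = 0.00731, and adjusted p = 0.563 with an estimated correlation). The sulfate transport gene *cysT* rose by 3.51 (SE 0.27) and the cysteine synthase gene *cysM* by 2.28 (SE 0.13), while *cysB*, the activator of the pathway, fell by 1.55 (SE 0.10). With library totals 20 genes of this list were higher and 1 was lower. Heat shock and chaperone genes were higher at 13 of 16 members and lower at 1 (median 1.66, camera adjusted p = 0.00595, and adjusted p = 0.563 with an estimated correlation). The chaperone genes *htpG* (3.25, SE 0.22) and *groES* (2.62, SE 0.17) rose, and *clpA*, of a protease subunit, fell by 2.48 (SE 0.12).

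Of the multidrug efflux genes, 16 of 32 fixed entries were matched, and 10 of these were higher and 5 were lower with DAS (median 0.63, camera adjusted p = 0.0303, and adjusted p = 0.467 with an estimated correlation). The highest rises were those of *mexC*, *mexD* and *oprJ*, which form 1 pump, and of their repressor gene *nfxB* (2.76, SE 0.15). *mexE* rose by 0.83 (SE 0.13), whereas *mexG* of another pump operon fell by 2.02 (SE 0.13). The call of this list was lost without control replicate 1, control replicate 2 or DAE replicate 3, and in limma fits of the FPKM values. Its adjusted p ranged from 0.00337 to 0.292 over the alternative fits.

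The remaining 11 lists were not called with DAS, at camera adjusted p of 0.086 to 0.962. Cobalamin genes were higher at 12 of 15 members (median 0.66), respiration and ATP synthase genes at 26 of 43 with 7 lower (0.45), and tricarboxylic acid cycle genes at 11 of 19 with 5 lower (0.51). Oxidative stress genes were higher at 10 of 18 and lower at 3 (0.54), and the catalase gene *katB* was at 0.17 (SE 0.13, adjusted p = 0.236). It was called higher with library totals (0.644) and in the limma fits without centring or quantile normalization, with adjusted p from 0.000399 to 0.782 over the alternative fits. Type III secretion genes were lower at 19 of 32 and higher at 4 (-0.66), type IV pili genes lower at 16 of 28 and higher at 7 (-0.43), and filamentous prophage genes lower at 6 of 11 and higher at 3 (-0.53). Iron uptake genes other than siderophores were lower at 6 of 15 and higher at 3, alcohol oxidation genes lower at 3 of 10 and higher at 2, and phosphate starvation genes lower at 4 of 13 and higher at 1. The last 3 lists had medians of -0.10, -0.15 and -0.21. With library totals the medians of these 3 lists, of the type IV pili genes and of the first type VI locus were positive. The splits then were 7 higher and 2 lower for iron uptake, 4 and 2 for alcohol oxidation, 5 and 3 for phosphate starvation, 11 and 7 for type IV pili, 10 and 13 for type III secretion, 5 and 4 for the filamentous prophage and 14 and 3 for the tricarboxylic acid cycle. For the first type VI locus (median -0.10), the direction given by camera was upward. Respiration, cobalamin and type III secretion genes were called with DAS in the limma fits of FPKM values, and respiration genes also without control replicate 1 (adjusted p = 0.0469). Over the alternative fits their adjusted p ranged from 0.00247 to 0.204, from 0.0268 to 0.231 and from 0.00918 to 0.178. Adjusted over the list alone, counts were the same as over all genes for 15 of the 16 called lists and 8 of the 11 others.

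**Figure D2:**
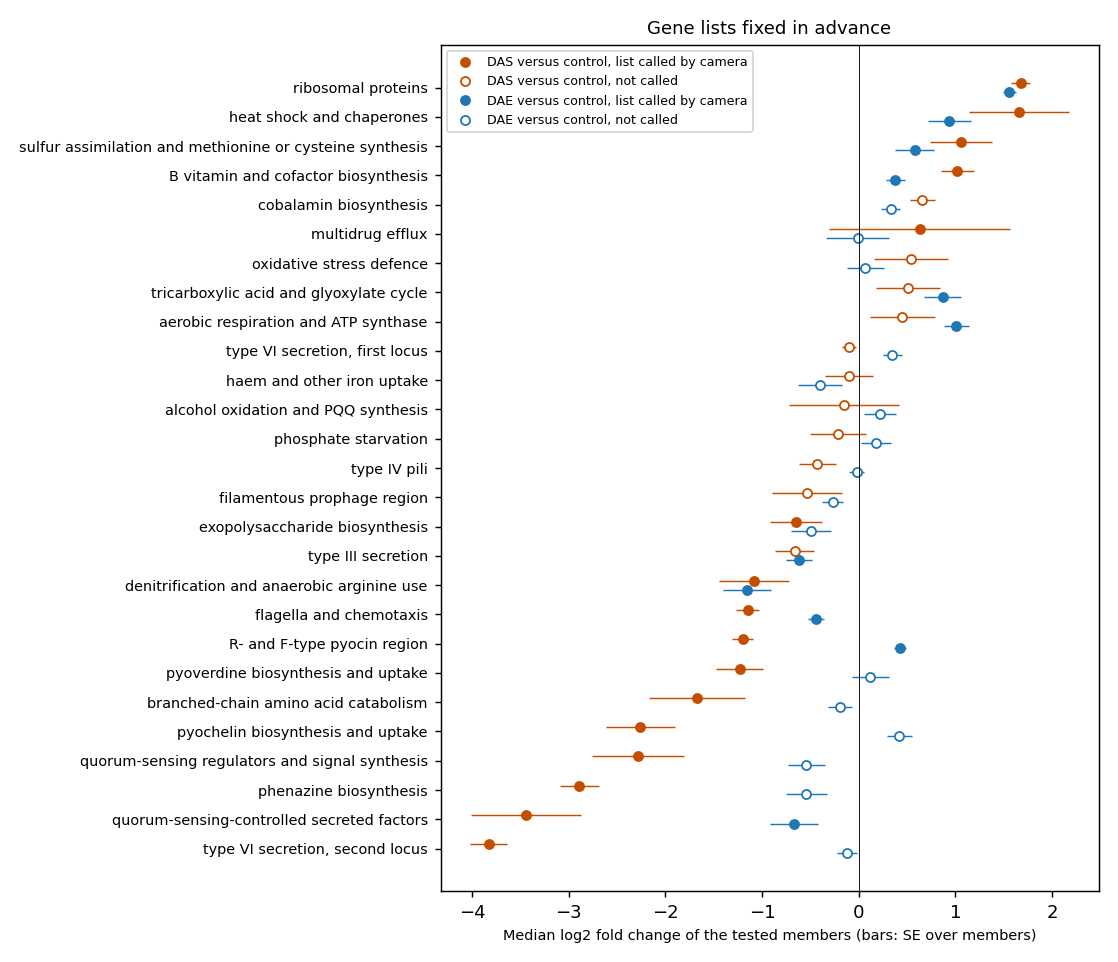
Median log2 fold change of each of the 27 gene lists with DAS (orange) and DAE (blue) against the controls, with the standard error of the median over list members (bars). Filled symbols mark lists called by camera. Ribosomal protein genes lay at 1.68 and 1.56, while the second type VI locus lay at -3.83 with DAS and at -0.12 with DAE.

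The next comparison asked the same of DAE, at the same dose and time. Ribosomal protein, respiration and tricarboxylic acid cycle genes were mostly higher with DAE. Genes of secreted factors, of type III secretion and of the joint list of denitrification and anaerobic arginine use were mostly lower. In that joint list the arginine genes *arcA* and *arcB* overlapped with controls. All lists named here were called by camera with its preset correlation, and none was called with an estimated correlation (adjusted p = 0.259 to 0.596). The largest rise was that of PA1168 (1267282 to 1267602), which encodes a hypothetical protein, from 397 ± 63.7 to 4310 ± 1100 CPM (log2 fold change 3.44, SE 0.21, adjusted p = 2.68e-07). The adjacent lipoxygenase gene PA1169 rose from 450 ± 28.4 to 4680 ± 646 CPM (3.38, SE 0.14). A neighbouring pair of hypothetical genes, PA4140 and PA4139, rose by 3.26 (SE 0.13) and 2.72 (SE 0.15) on the log2 scale, the latter to 9630 ± 1570 CPM. The largest falls were those of PA3441, annotated as a molybdopterin-binding protein (-4.38, SE 0.13), and of the molybdenum cofactor gene *moeA1* (-4.17, SE 0.36), whose controls varied widely at 293 ± 158 CPM. PA3441 and *moeA1* were low with DAS as well, at 11.7 to 11.9 CPM and 23.6 to 30.6 CPM. With DAE they were at 9.35 to 11.1 CPM and 12 to 22.5 CPM. *lecA* (-3.26, SE 0.24) and *flp* (-3.45, SE 0.24) also fell with DAE, but less than with DAS. In edgeR's test 3183 genes passed, 1599 higher and 1584 lower, and 761 of them changed at least 2-fold. With library totals, which placed the median gene at -0.08, the split was 1374 higher and 1720 lower.

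Secreted factors under quorum-sensing control were lower with DAE at 19 of 25 genes and higher at 4, with a median of -0.67 (camera adjusted p = 3.37e-05, and adjusted p = 0.259 with an estimated correlation). *aprA* fell from 31100 ± 1140 to 6570 ± 1020 CPM, *lasB* by 0.98 (SE 0.12) and *rhlA* by 1.73 (SE 0.24) on the log2 scale. The 4 higher genes, named after their values were seen except *hcnA*, were the cyanide genes *hcnA* (0.49, SE 0.11), *hcnB* (0.90) and *hcnC* (0.51) and the lipase gene *lipA* (1.01). Of the 19 genes for regulators and signal synthesis 11 were lower and 4 were higher, and this list was not called (median -0.54, camera adjusted p = 0.18). In 1 limma fit it was called, within a range of 0.0303 to 0.256 over the alternative fits. *lasI* rose from 524 ± 94.5 to 1510 ± 152 CPM (1.52, SE 0.14, adjusted p = 4.08e-06). *lasR* (-0.54, SE 0.10), *rhlR* (-0.56, SE 0.12) and *mvfR* (-0.60, SE 0.09) fell. *rhlI* was at -0.14 (adjusted p = 0.368) and *pqsA* at 0.13 (adjusted p = 0.585). Phenazine genes were lower at 9 of 17 and higher at 1 and were not called as a list (median -0.54, camera adjusted p = 0.121), with *phzM* lower at -0.54 (SE 0.13) and *phzS* at 0.32 (adjusted p = 0.141). *phzS* was called higher without control replicate 2 or DAE replicate 1, with adjusted p from 0.0434 to 0.51 over the alternative fits. Summed over both copies, the 7 phz gene pairs were at 0.495 to 0.837 of their control level, and 4 of them were below every control library. The 1 higher gene, *phzB1* (1.14), named after its values were seen, belongs to the pair at 0.837. The list was called without DAE replicate 3 (adjusted p = 0.0125, with 11 lower) or control replicate 3 (adjusted p = 0.0494), within a range of 0.0125 to 0.224 over the alternative fits.

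Ribosomal protein genes were higher with DAE at 53 of 53 members (median 1.56, camera adjusted p = 7.52e-37, and adjusted p = 0.259 with an estimated correlation), such as *rplF*, which went from 225 ± 32.2 to 818 ± 49.8 CPM. Respiration and ATP synthase genes were higher at 33 of 43 and lower at 2 (median 1.01, camera adjusted p = 7.86e-12, and adjusted p = 0.259 with an estimated correlation). The succinate dehydrogenase genes *sdhB* (1.64, SE 0.11) and *sdhA* (1.56, SE 0.12) rose, as did *atpE* (1.47, SE 0.11). Tricarboxylic acid cycle genes were higher at 14 of 19 and lower at 1 (median 0.87, camera adjusted p = 3.39e-07, and adjusted p = 0.374 with an estimated correlation), with the citrate synthase gene *gltA* at 1.70 (SE 0.11). Sulfur assimilation was higher at 16 of 25 genes and lower at 3 (median 0.58, camera adjusted p = 0.000853), B vitamin synthesis at 21 of 38 with 2 lower (0.38, 0.00412) and heat shock at 12 of 16 with 1 lower (0.94, 0.00362). Each of these 3 lists was at adjusted p = 0.596 with an estimated correlation. The gene values included *cysN* at 1.72 (SE 0.17), *bioB* at 0.73 (SE 0.14), *thiC* at 0.49 (SE 0.10) and *htpG* at 1.62 (SE 0.21). The pyocin region was higher at 17 of 34 genes (median 0.43, camera adjusted p = 0.0203, and adjusted p = 0.755 with an estimated correlation). This call was lost without DAE replicate 1, at adjusted p = 0.111, within a range of 0.000177 to 0.111 over the alternative fits.

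Denitrification and anaerobic arginine genes were lower with DAE at 21 of 31 and higher at 1 (median -1.16, camera adjusted p = 0.000109, and adjusted p = 0.596 with an estimated correlation). The nitrate reductase genes *narG* (-3.10, SE 0.29) and *narH* (-2.62, SE 0.26) and the transporter gene *narK2* (-3.24, SE 0.34) fell, and were low with DAS as well. The arginine deiminase gene *arcA* was at 13600 to 21000 CPM with DAE against 15700 to 19500 CPM in controls. *arcB* was at 9930 to 17500 CPM against 15200 to 17400 CPM, and *arcC* at 5240 to 8720 CPM against 8820 to 11300 CPM. Flagellar genes were lower at 23 of 39 (median -0.44, camera adjusted p = 5.6e-05, and adjusted p = 0.596 with an estimated correlation), including *flhF* (-1.28, SE 0.12) and *fleR* (-1.11, SE 0.12). Type III secretion genes were lower at 21 of 32 (median -0.62, camera adjusted p = 5.6e-05, and adjusted p = 0.259 with an estimated correlation), including the translocon genes *popD* (-2.18, SE 0.14) and *popB* (-1.89, SE 0.14). Pyoverdine genes (6 of 17 higher, 2 lower) and pyochelin genes (4 of 9 higher) were not called as lists, apart from pyochelin without control replicate 3 (adjusted p = 0.0494, range 0.0494 to 0.358), although *pvdS* rose by 1.22 (SE 0.17). *pchR* was at 0.06, *mexE* at -0.24, *katB* at -0.10 and *ribD* at 0.07, and none of these passed. *mexG* fell by 2.54 (SE 0.14) and *folE2* rose by 0.40 (SE 0.10). The second type VI locus was lower at 4 of 15 genes and higher at 2 (camera adjusted p = 0.509), against 5 and 1 with library totals. Exopolysaccharide genes were lower at 18 of 31 and higher at 7, and were not called (camera adjusted p = 0.18). Among the higher ones, *pelD* was at 30.5 to 35.2 CPM with DAE and 20.7 to 27.2 CPM with DAS. Its control libraries were at 6.03 to 6.81 CPM. The 16 lists not called with DAE had camera adjusted p of 0.121 to 0.939. By camera with an estimated correlation 0 lists were called, where 4 had an unadjusted p under 0.05. Adjusted over the list alone, counts matched those over all genes for 7 of the 11 called lists, and 34 respiration, 15 tricarboxylic acid cycle, 16 pyocin and 13 heat shock genes were higher.

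The direct comparison of the analogs at the same dose and time asked how the exchange of sulfur for oxygen went with the response. Quorum-sensing genes and those of the second type VI locus were lower with DAS than with DAE, and *fhp*, *norC* and the genes of the *mexC* operon were higher. The largest gap upward was that of *fhp*, at 1730 ± 469 CPM with DAS and 9.22 ± 1.60 CPM with DAE (log2 difference 7.55, SE 0.24, adjusted p = 9.23e-11). *mexC* was higher by 7.23 (SE 0.18), *mexD* by 5.73 (SE 0.23), *oprJ* by 5.02 (SE 0.20) and the reductase gene *morB* by 4.79 (SE 0.21). The nitric oxide reductase gene *norC* (582015 to 582455) was at 646 ± 20.5 CPM with DAS and 30.4 ± 36.9 CPM with DAE (4.42, SE 0.75). Without DAE replicate 1, its highest DAE library, the difference was 6.15. The largest gap downward was that of PA1168, at 8.74 ± 1.38 CPM with DAS and 4310 ± 1100 CPM with DAE (-8.95, SE 0.28, adjusted p = 7.72e-11). Next came PA4139 (-7.13, SE 0.18) and a run of adjacent genes, among them PA3332 (-7.50, SE 0.16), PA3334 (-7.08, SE 0.15), *fabH2* (-6.62, SE 0.15) and the cytochrome P450 gene PA3331 (-6.56, SE 0.14). In edgeR's test 3796 genes differed, 1945 higher and 1851 lower with DAS, and 1553 differed at least 2-fold. With library totals, which placed the median gene at 0.586, the split was 3395 higher and 1053 lower.

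**Figure D3:**
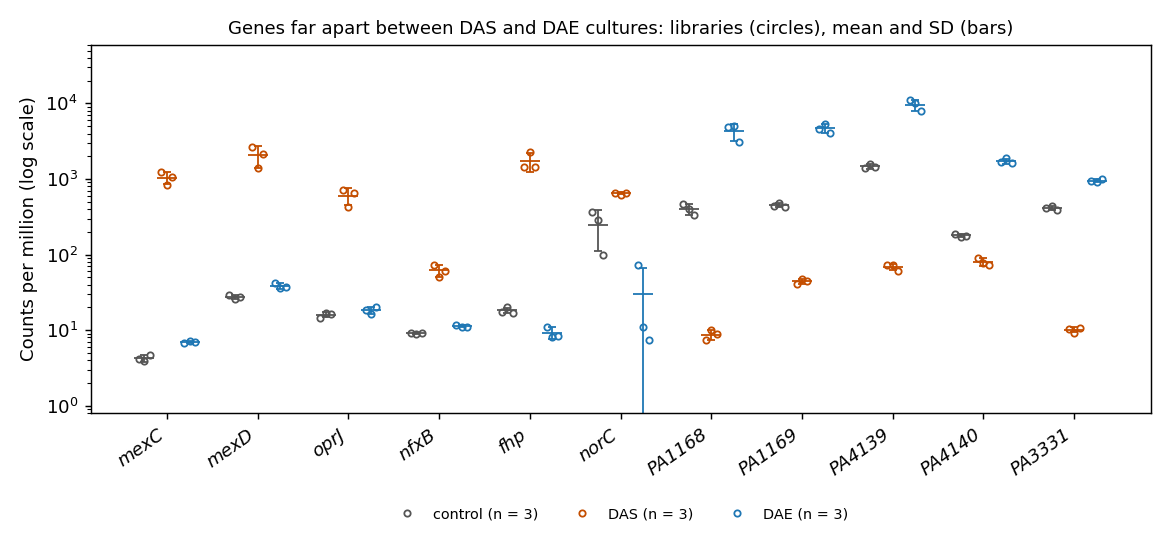
Level of 11 genes that lay far apart between DAS and DAE cultures, in CPM on a log axis, for the 3 libraries of each group (circles, control grey, DAS orange, DAE blue) with the group mean and SD (bars). *mexC* was at 1050 CPM with DAS against 6.97 CPM with DAE, and PA1168 at 8.74 CPM against 4310 CPM. The SD of *norC* with DAE exceeds its mean, so its lower bar runs off the axis.

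All 19 quorum-sensing regulator and signal genes were lower with DAS than with DAE (median -1.78, camera adjusted p = 1.66e-16, and adjusted p = 0.00759 with an estimated correlation). *pqsA* differed by -3.52 (SE 0.21), *rhlI* by -1.78 (SE 0.14), *rhlR* by -1.72 (SE 0.13), *mvfR* by -1.52 (SE 0.09), *lasI* by -1.02 (SE 0.14) and *lasR* by -0.95 (SE 0.10). Secreted factors were lower at 22 of 25 genes and higher at 1, *plcN*, named after its values were seen (median -2.90, camera adjusted p = 1.33e-21, and adjusted p = 0.00759 with an estimated correlation). *lecA* differed by -5.35 (SE 0.29), *lasB* by -5.05 (SE 0.14), *rhlA* by -3.06 (SE 0.25) and *hcnA* by -2.88 (SE 0.13). The second type VI locus was lower at 15 of 15 genes (median -3.76, camera adjusted p = 3.96e-29, and adjusted p = 0.00967 with an estimated correlation).

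Other lists also differed between the analogs by camera, but their calls were lost with an estimated correlation. Phenazine genes were lower with DAS at 16 of 17 (median -2.40, camera adjusted p = 1.79e-06, and adjusted p = 0.377 with an estimated correlation), with *phzM* at -2.17 (SE 0.14) and *phzS* at -3.04 (SE 0.19). Pyochelin genes were lower at 9 of 9 (median -2.89, camera adjusted p = 1.29e-08, and adjusted p = 0.215 with an estimated correlation) and pyoverdine genes at 16 of 17 (median -1.78, camera adjusted p = 3.56e-05, and adjusted p = 0.568 with an estimated correlation). The regulator genes *pvdS* and *pchR* differed by -1.97 (SE 0.17) and -0.86 (SE 0.18), the latter no longer called with library totals at -0.32. Pyocin region genes were lower at 34 of 34 (median -1.64, camera adjusted p = 1.64e-06, and adjusted p = 0.601 with an estimated correlation). Flagellar genes were lower at 33 of 39 and higher at 2 (median -0.63, camera adjusted p = 0.00562, and adjusted p = 0.787 with an estimated correlation). With library totals only 11 flagellar genes were lower and 7 were higher (median -0.09). Branched-chain amino acid genes were lower at 13 of 14 (median -1.59, camera adjusted p = 0.00562, and adjusted p = 0.601 with an estimated correlation). Higher with DAS were B vitamin genes, at 27 of 38 with 3 lower (median 0.68, camera adjusted p = 0.00108, and adjusted p = 0.377 with an estimated correlation), and efflux genes, at 12 of 16 with 1 lower (median 0.57, camera adjusted p = 4.48e-05, and adjusted p = 0.136 with an estimated correlation). *bioB* differed by 1.61 (SE 0.15), *thiC* by 0.67 (SE 0.10), *ribD* by 0.40 (SE 0.15), *folE2* by -0.32 (SE 0.10), *mexE* by 1.07 (SE 0.14) and *mexG* by 0.52 (SE 0.15). The call of *ribD* was lost without DAE replicate 1 or 2 or DAS replicate 1 or 2, and that of *mexG* without DAE replicate 3. The value of *folE2* was 0.22 with library totals. Adjusted over the list alone, counts matched those over all genes for 10 of the 11 called lists, and 13 efflux genes were higher.

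Other gene groups were not called different between the analogs, and the list values given here depended on the scaling. Ribosomal protein genes had a median difference of -0.02, with a 95% interval over members of -0.19 to 0.15, and 15 were higher and 6 lower with DAS (camera adjusted p = 0.283). With library totals 44 were higher and 0 lower (median 0.52, adjusted p = 0.177). Limma on FPKM values called this list higher with DAS with no rescaling (adjusted p = 0.0303) and with quantile normalization (48 higher, median 0.76, adjusted p = 1.13e-06), within a range of 1.13e-06 to 0.493 over the alternative fits. Type III secretion genes had a median of 0.00 (-0.24 to 0.24) with 7 higher and 8 lower, against 0.55 with 17 higher and 1 lower with library totals. Denitrification and arginine genes had a median of 0.26 (-0.63 to 1.15) with 9 higher and 9 lower, against 0.81 with 17 and 6. Respiration genes had a median of -0.59 (-1.21 to 0.03) with 7 higher and 28 lower, against -0.06 with 12 and 13. Tricarboxylic acid cycle genes had a median of -0.36 (-0.75 to 0.03) with 2 higher and 11 lower, against 0.18 with 7 and 5. The 16 lists not called between the analogs had camera adjusted p of 0.0707 to 0.751. Of these, respiration, heat shock and exopolysaccharide genes were called in 8, 8 and 7 alternative fits, with adjusted p from 0.00515 to 0.206, from 0.000795 to 0.102 and from 0.000795 to 0.129. *katB* differed by 0.28, with an interval of 0.02 to 0.54 and an adjusted p of 0.0766. It was called higher with DAS in some fits, among them library totals (0.818), with adjusted p from 6.3e-05 to 0.332 over the alternative fits. For the ribosomal genes, and for the iron uptake genes other than siderophores, the mean over members and the direction given by camera were positive although the median was negative, and for the denitrification list camera pointed downward.

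Calls against the shared controls overlapped. Of the 5567 genes, 1254 were called higher and 1231 lower with both compounds, 2485 in all. Lists that were independent would share 656.9 higher and 604.9 lower genes, and 100 simulations of unchanged groups against the same controls gave a median of 0 and at most 1 gene. The controls were too few to be split, so part of the excess of shared calls may come from the shared libraries. Fold changes correlated across genes at 0.598, against a simulated median of 0.507, with a covariance of 0.658 against 0.0144. Among the genes called in both in the same direction, 82.1% changed more with DAS, and the median ratio of the DAE change to the DAS change was 0.596. Among these genes, 468 higher and 387 lower ones were not called different between the analogs. A further 287 genes were called in opposite directions, where independent lists would give 1261.4.

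**Figure D4:**
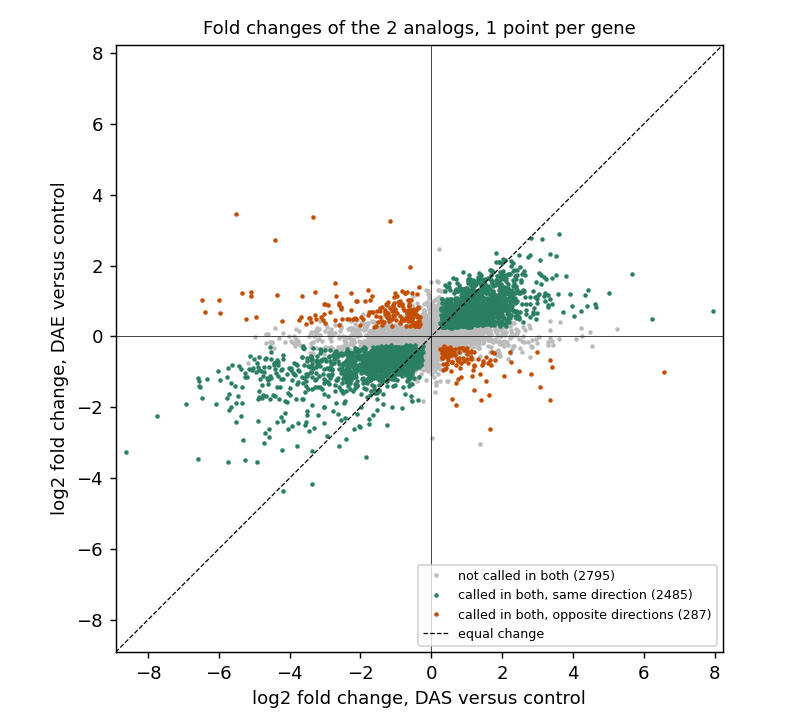
Log2 fold change against the controls with DAS (horizontal axis) and DAE (vertical axis) for the 5567 tested genes, 1 point per gene. Green points are the 2485 genes called in both in the same direction, orange points the 287 called in opposite directions, grey points the rest, and the dashed line marks equal change.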

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

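The test of opposite direction, and the fit with library totals used beside it, were chosen after the results were seen. The other tests of this part were fixed before.

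Some genes had opposite responses to the analogs, at 287 calls against 1261.4 for lists that were independent. In edgeR's test, 178 genes were called lower with DAS and higher with DAE than in controls. A further 109 were called higher with DAS and lower with DAE. All of them were called in the direct contrast, which follows almost from the opposite calls and adds no separate support. Among the 178 were PA1168 (-5.50 with DAS and 3.44 with DAE) and PA4139 (-4.42 and 2.72). Among the 109 were *fhp* (6.56 and -0.99) and *norB* (1.65 and -2.61). At *norB* both groups of the latter value varied widely, with 181 to 765 CPM in controls and 29.3 to 173 CPM with DAE. DAE could be a weaker form of the response to DAS, in which case no gene would move oppositely. Judged by the larger of a gene's p-values, adjusted over all genes, 92 genes passed in opposite directions with TMM and 85 with library totals. The division depended on scaling, with 67 lower and 25 higher with DAS under TMM, against 37 and 48 with library totals. Some genes therefore did not pass under both scalings, and those that did were not counted. Under each scaling the counts argue against a weaker form of the DAS response for a set of genes, without settling which genes. Shared controls push fold changes together and so would not produce opposite directions. Of all genes called with DAE, 78.1% were called in the same direction with DAS. This lies between the bounds set in advance (80% for a single response, 50% against it). For the transcriptome as a whole this test left a single response of different size open. List medians, compared after they were seen, did not share a common scale. The second type VI locus had medians of -3.83 with DAS (SE over members 0.188) and -0.12 with DAE (0.108). Ribosomal protein genes had medians of 1.68 (0.0986) and 1.56 (0.0659). With library totals these medians were -3.35 and -0.19, against 2.16 and 1.5. The values argue against a single scaled response for these lists. The covariance of fold changes was 0.658 and the highest of 100 values simulated with unchanged groups and the same controls was 0.0168, so noise in the shared controls does not account for most of the covariance, while its part in the count of shared calls stays open, as the simulated counts (at most 1 gene) leave out real effects.

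The 6 libraries of a comparison allow only 10 splits into 3 and 3, too few for a share under 0.05. For DAS versus control the real split called 4327 genes in fits of the 6 libraries, for DAE versus control 3266, and for DAS versus DAE 3786. In each comparison the real split was the 1 split with as many genes. The highest of the other splits called 0 in each by edgeR, with at most 56, 340 and 39 genes at an unadjusted p under 0.05. Every other split mixed libraries of both groups on each side, so the group difference entered its spread. The 0 calls thus do not show what a split of unaffected cultures would give.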

How the results depend on the processing

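Library totals in place of TMM factors, and naming of genes outside the fixed rule, were chosen after the data were seen. Counts of genes called stayed within 1.5 times the reported ones under every alternative except a threshold on fold change. With at least 2-fold change, 2402 genes passed for DAS versus control, 761 for DAE versus control and 1553 for DAS versus DAE, fewer by construction. With camera's estimated correlation 3, 0 and 3 lists were called in these comparisons, and with fry, which does not compare a list with other genes, 26, 19 and 19. Without each library in turn, calls ranged from 4195 to 4419, from 2700 to 3239 and from 3468 to 3904 genes, from 14 to 16, from 10 to 13 and from 11 to 12 lists, and from 2169 to 2501 genes called in both in the same direction.

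With the replicate block 4459, 3250 and 3823 genes were called. Whether the numbers pair the cultures is undecided. Correlations of deviations ran from -0.21 to 0.357 between same-numbered libraries and from -0.339 to 0.279 between differently numbered ones.

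Of 259 pairs of a named gene and a comparison, 246 kept direction and call under every alternative run. Many of these pairs were named for a large change or a small adjusted p in the main fit, so their stability largely follows from that choice. All pairs that did not keep both belong to genes named in every case, whatever their values. These genes were *pvdS*, *pchR*, *folE2*, *katB*, *phzS*, *ribD*, *mexE* and *mexG*. The pooled share therefore says little about genes not chosen for their values. Values that turned sign were all outside the call in the alternative. For *pchR* with DAE they were -0.071 without control replicate 1 and -0.043 without DAE replicate 3, against 0.182 without control replicate 3. For *ribD* with DAE they were -0.012, -0.013 and -0.010 in limma fits with pseudocounts of 1, 0.1 and 5, -0.012 with no filter or with centring, -0.018 without control replicate 1 and -0.097 without DAE replicate 3, against 0.182 without DAE replicate 2. For *mexE* with DAE it was 0.067 with quantile normalization. For *folE2* between the analogs they were 0.221, 0.222 and 0.217 with those pseudocounts, 0.221 with no filter, 0.017 with quantile normalization and 0.222 with library totals. The cause was not tested. Calls were gained in some fit by *katB* and *folE2* with DAS, *phzS* with DAE and *katB* between the analogs, with lowest adjusted p of 0.000399, 0.000512, 0.0434 and 6.3e-05. *pvdS* and *pchR* lost their calls with DAS in limma fits without centring or quantile normalization and with library totals, with adjusted p ranging over all alternatives from 0.000255 to 0.164 and from 1.86e-05 to 0.156. No called list changed the sign of its median, and 3 lists lost a call in some fit. Calls were gained in some fit by 3 lists for DAS versus control, 5 for DAE versus control and 6 for DAS versus DAE, most often in limma fits. At most 62.7% of simulated 1.5-fold changes were recovered in any comparison. The simulations changed 200 genes of 5567, far fewer than were called here, so this share need not hold for these comparisons.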

Other observations

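The test of growth phase between the analogs was chosen after the result was seen, and the fit with library totals was added after the files were seen. The stationary-phase markers were chosen once the tables were at hand, so the growth-phase test of DAS against controls was stated before its values were seen but not before the tables were. The scaling and gene length explanations were stated before their values were seen. The most counted genes, with *aprA* first in controls, and the correlations between libraries had been seen before these explanations were written, but not before the gene lists were fixed.

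Genes of terminal oxidases are members of the respiration list, which was described above only as a whole. Those named here were chosen after their values were seen and were not tested as a group. With DAS the cytochrome bo3 genes *cyoA* and *cyoD* rose by 2.95 and 2.78 on the log2 scale, while *ccoN2* and *ccoO2* of a cbb3 oxidase were at -2.26 and -3.03 and the aa3 oxidase genes *coxA* and *coxB* at -4.81 and -4.40. The genes *ccoN1* and *ccoO1* of the other cbb3 oxidase rose with both compounds, by 1.32 and 0.70 with DAS and by 1.67 and 1.35 with DAE. With DAE *ccoN2* and *ccoO2* rose by 1.24 and 0.92, *cyoD* was at 0.23 without a call, and *coxA* was at -0.98. Among oxidative stress genes, the catalase gene *katA* was at -3.26 with DAS and at 0.04 without a call with DAE, whereas *ohr*, of organic peroxide resistance, rose by 2.38 with DAS and by 0.73 with DAE.

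Quorum-sensing genes were lower with DAS than in controls, with a median of -3.44 for the secreted factors. Scaling and gene length do not account for this, as the median was -2.96 with library totals and -3.46 after removal of a trend on coding length, which moved 1072 of 5567 genes by at least 0.1 on the log2 scale and no secreted factor by more than 0.09. A difference in growth phase may account for part or all of it. A list of 9 stationary-phase markers, among them *rmf* (-2.25) and *rpoS* (-2.23), had a median of -2.23 (SE over members 0.749) with DAS. Of them 8 were lower, while ribosomal protein genes were higher, as that explanation needs. *katE*, *coxA* and *coxB* of the markers are also in other lists, and no cell density is among the labels, so an effect of the compound on quorum sensing itself stays open too.

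Between the analogs, growth phase cannot be told apart from other explanations. The secreted factors were lower with DAS than with DAE by a median of -2.90, and the stationary-phase markers by -1.75 with 9 of 9 lower. A later growth phase with DAE would be expected to go with lower ribosomal protein genes. But these differed by a median of -0.02 (SE over members 0.0845) with TMM and by 0.52 with library totals, so that the outcome rests on the scaling. With DAE against controls the ribosomal protein genes were higher by 1.56, while the stationary-phase markers were at -0.08 (SE over members 0.31).

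The descriptive columns of the deposited tables name other organisms than the one sequenced. Of 4616 protein descriptions taken from a general database, 4610 name an organism and 0 name *Pseudomonas*. *Beauveria*, a genus of fungi, is named in 1388, and 775 of 3683 orthology entries name mucin-19. These columns were not used for any result.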
